A study of Xenopus laevis with 9 samples.

How the data were processed

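Gene expression was measured on Affymetrix arrays of Xenopus laevis, the African clawed frog. RNA came from 3 tissues dissected from embryos at stage 26 and placed in Trizol, with 75 to 100 embryos pooled in each sample. Groups and replicate numbers were taken from the labels, which gave 3 samples of primary mouth (numbered 1a, 2 and 3), 3 of anterior dorsal tissue and 3 of ventral and cement gland tissue. The labels do not say what the letter in 1a stands for. They also do not say that samples of a tissue came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

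The deposited table holds 1 signal intensity per probe set and array on a linear scale, which the authors computed with MAS5 per the submitters' processing notes. The MAS5 version and its settings are not given in the sources used here. MAS5 corrects each array for background and summarises the perfect-match and mismatch probes of a probe set. The mean signal without the top and bottom 2% of probe sets was 150 on all 9 arrays, so the deposited scaling was kept. Detection calls were not analysed here. It is therefore open which low signals lay above background, and levels near the bottom of the scale were not read as absence. Median signals were 50.9 to 59.2 per array. With 3 arrays per tissue, the number of arrays limits the precision of every value.

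The table has 15611 probe sets, of which 120 are controls. The platform annotation used here gives 1 gene symbol for 9304 probe sets, several for 195 and none for 5992 (no gene was named from the last 2 kinds). By gene ID, 9227 of the probe sets with 1 symbol matched the RefSeq gene table of assembly Xenopus_laevis_v10.1, which updated 2 symbols. That table was used for names only, and no coordinates are given because the array's probes were not placed on that assembly. Of the named probe sets, 205 carry only a clone or locus name and were counted but not named. Another 85 carry a database placeholder of XB and a number, which were ranked with the named genes, so 1 of the 10 largest decreases in both contrasts against ventral tissue was left unnamed. Xenopus laevis carries 2 copies of many genes, written .L and .S. Probe sets may detect both copies, so differences between copies are uncertain.

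Signals were analysed as log2(signal + 16). Control probe sets were left out. A probe set was tested if at least 3 of the 9 arrays lay above the 40th percentile of their own array, a signal of 30.9 to 35.8, which left 10011 probe sets, 6540 of them with 1 symbol. One linear model with a mean per tissue was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of the variance on the mean signal, 6 residual degrees of freedom). Each of the 3 pairwise contrasts was tested on both sides with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on the log2(signal + 16) scale, which understates the change of genes with low signal. A probe set was counted as higher, or lower, than in both other tissues when it passed both primary mouth contrasts in that direction. Errors beside signals are SD over 3 arrays, and errors beside log2 fold changes are standard errors of the model.

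The test, the filter, the gene lists and the rule for the genes named were fixed before the data were examined. Genes named are, for each contrast, the 10 with the largest log2 fold change in each direction among those past the threshold whose arrays did not overlap between the tissues. To these were added the 15 genes highest, and the 10 lowest, against both other tissues by the smaller of both fold changes. Also named were frzb, frzb2, pitx1, otx2, shh, ag1 and agr2 whatever their values, and up to 4 examples per gene list and contrast with the largest changes. The probe set with the highest mean stood for a gene. Of 736 symbols with several tested probe sets, 0, 1 and 2 had probe sets called in opposite directions against anterior dorsal tissue, against ventral tissue, and between these 2 tissues, and 50, 87 and 127 had some probe sets past the threshold and others not.

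Gene lists were 22 in number. They covered primary mouth and anterior ectoderm, cement gland, forebrain and neural tube, eye and lens, cranial neural crest, foregut endoderm and liver, epidermis, ciliated cells and ionocytes, skeletal muscle and notochord, heart and ventral blood, primitive myeloid cells, Wnt, BMP and TGF-beta, Hedgehog, retinoic acid and FGF signalling, basement membrane and extracellular matrix, matrix proteases and inhibitors, cell cycle, apoptosis, heat shock and stress, and Hox genes. Members of both homeologous copies were counted separately. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, which gave 63 tests adjusted together. The Hox list had 3 tested members and was only described. The primary mouth list was drawn up from knowledge of primary mouth genes that may rest in part on these samples, so its direction is not independent evidence.

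Replicate numbers were checked for pairing by the correlation of each sample's deviation from its tissue mean. For anterior dorsal against ventral tissue the same-numbered pairs correlated at 0.68, 0.51 and 0.54. The pairing of these 2 tissues comes from this correlation, since the labels state no shared clutch or day. A fit with the number as a block is among the alternatives. The spiked-in and housekeeping control probe sets were examined for batches, and the batches found were added to the fit after seeing the data.

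Alternatives were quantile normalization, offsets of 1 and 64, no filter, a filter at the 60th percentile, no variance trend, the replicate block, only the 2 tissues of a contrast in the fit, a 2-fold minimum and leaving out each array in turn. The fits by batch, and the list tests without each array, were chosen after seeing the data. The fit was tested on simulated data for the primary mouth contrasts over 10011 genes. It recovered 85 of 100 genes changed by 1 on the log2 scale against anterior dorsal tissue and 84 of 100 against ventral tissue, and 100 of 100 changed by 2 in each, with 13 and 12 false calls. The simulated noise was independent between genes and held no batch, so these rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.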

Results

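Expression was measured in 3 tissues of Xenopus laevis embryos at stage 26, a tailbud stage. The primary mouth is the first opening of the embryonic mouth and forms where ectoderm and endoderm meet at the front of the head. The tissues on either side of it were an anterior dorsal piece and a ventral piece that included the cement gland, a mucus-secreting organ of the head ectoderm. Each tissue was represented by 3 samples, and each sample was hybridised to its own array. Signals ran from 0.0712 to 15620 units, and no pair of arrays held identical values. Pearson correlations of log2 signals across probe sets were 0.938 to 0.985 between arrays of the same tissue and 0.839 to 0.947 between arrays of different tissues.

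The control probe sets divided the arrays into 2 batches that cut across the tissues. The ratio of 3' to 5' signal of beta-actin, which rises when transcripts are shortened or incompletely copied, was 5.48 to 11.2 in 4 arrays (anterior dorsal 1, primary mouth 1a and 2, ventral 1) and 1.47 to 2.03 in the other 5. The spiked-in dap control read 2268 to 3008 in the same 4 arrays and 540.1 to 858 in the others. Within tissues, 55.1% of the variance lay on 1 component, and 2565 of 10011 probe sets differed between the batches in limma (adjusted p under 0.05, with tissue in the model). Primary mouth had 2 arrays in the first batch and 1 in the second, whereas each flanking tissue had 1 and 2. Within a batch the spread therefore comes only from the tissues with 2 arrays, in the first batch from primary mouth alone. Counts with the batch as a term and within each batch are therefore given beside each count of probe sets. For gene lists the count with the batch as a term is given where it moved by over 1.5 times.

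**Figure D1:**
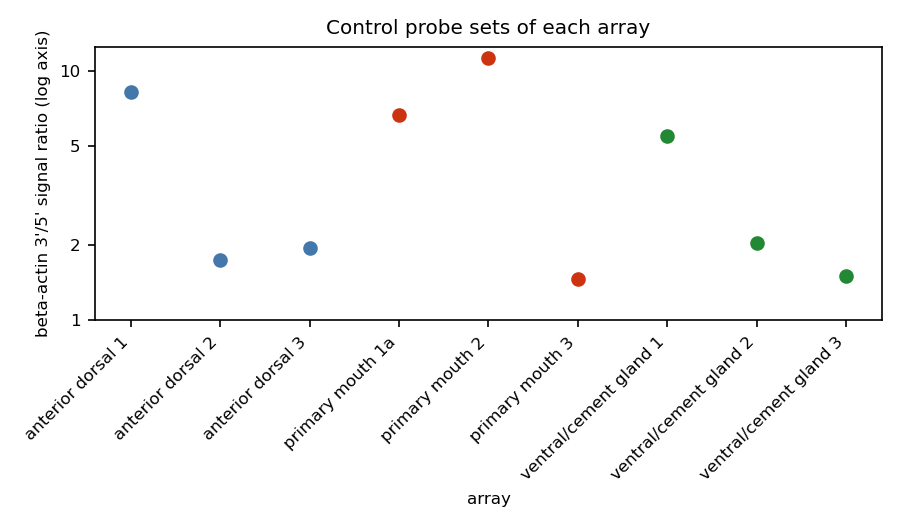
Ratio of 3' to 5' signal of the beta-actin control probe sets (log axis) for each of the 9 arrays, coloured by tissue. The ratio is 5.48 or more in 4 arrays and 2.03 or less in 5, and each tissue has arrays on both sides.

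The first comparison asked which genes were enriched in the primary mouth over both flanking tissues. The secreted Wnt antagonist frzb led, and both of its homeologs were higher. The signal of frzb.L (gene ID 399085) was 491 ± 387 (SD, n = 3) in primary mouth, 43.4 ± 17.8 in anterior dorsal and 30.5 ± 2.42 in ventral tissue. Its log2 fold changes were 2.86 ± 0.41 and 3.17 ± 0.41 (SE), with limma adjusted p = 0.000661 and 0.000256. For frzb.S (gene ID 734982) the signals were 306 ± 147, 28.5 ± 11.96 and 7.51 ± 2.90, and the log2 fold changes 2.76 ± 0.33 and 3.65 ± 0.33 (adjusted p = 0.000184 and 2.06e-05).

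The genes cpn1.S, kng1.L and nos1.L were among the 15 leading ones. Expression of cpn1.S (gene ID 398791), the catalytic subunit of the kinin-cleaving enzyme carboxypeptidase N, was 142 ± 48.5 in primary mouth against 17.9 ± 5.24 and 15.1 ± 2.98 (log2 fold changes 2.19 ± 0.22 and 2.30 ± 0.22, adjusted p = 4.84e-05 and 2.44e-05). For kng1.L (gene ID 494833), which encodes the kinin precursor kininogen, signals were 816 ± 255, 237 ± 36.8 and 93.1 ± 29.5 (log2 fold changes 1.67 ± 0.26 and 2.91 ± 0.26, adjusted p = 0.00113 and 1.66e-05). Neuronal nitric oxide synthase, nos1.L (gene ID 373705), read 599 ± 109, 219 ± 37.0 and 119 ± 17.7 (log2 fold changes 1.38 ± 0.19 and 2.18 ± 0.19, adjusted p = 0.000463 and 1.4e-05). These 3 genes belong to the primary mouth list, which may rest in part on these samples. So do both frzb copies, and pitx3.L and hesx1.L below.

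The homeobox genes pitx3.L and hesx1.L, known from the lens and from the anterior neural plate and pituitary respectively, were higher as well. Signals of hesx1.L were 61.3 ± 27.1 in primary mouth against 5.98 ± 5.495 and 7.75 ± 6.06 (log2 fold changes 1.79 ± 0.27 and 1.68 ± 0.27, adjusted p = 0.00102 and 0.00141). Those of pitx3.L were 117 ± 60.1, 19.2 ± 7.78 and 12.8 ± 3.35 (log2 fold changes 1.85 and 2.12, adjusted p = 0.000924 and 0.000289). Of receptors and ligands, the neurotrophin receptor ntrk2.L differed by 2.31 ± 0.21 and 2.17 ± 0.21 on the log2 scale, the endothelin receptor ednra.L by 2.19 ± 0.22 and 1.44 ± 0.22, and the growth factor fgf20.L by 2.34 ± 0.18 and 1.33 ± 0.18. The protocadherin pcdh8l.S (2.88 and 1.31) and the myelin protein gene pmp22.L (1.23 and 1.51) completed the adhesion and membrane genes. Over these 5 genes and both contrasts, adjusted p was 1.11e-05 to 0.0015.

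The 15 leading genes also held socs3.L and both irf1 copies. The cytokine feedback inhibitor socs3.L read 313 ± 87.8 in primary mouth against 75.5 ± 35.6 and 81.7 ± 28.4 (log2 fold changes 1.87 ± 0.30 and 1.75 ± 0.30, adjusted p = 0.00128 and 0.00179). The interferon regulatory factor irf1.S read 127 ± 6.78, 37.5 ± 14.9 and 30.1 ± 8.60 (log2 fold changes 1.46 ± 0.22 and 1.65 ± 0.22, adjusted p = 0.00102 and 0.000378). Its homeolog irf1.L varied more, with log2 fold changes of 1.67 ± 0.40 and 1.74 ± 0.40 (adjusted p = 0.0183 and 0.0108). The first irf1.L call was lost without anterior dorsal 2 (adjusted p = 0.0963), anterior dorsal 3 (0.0545) or primary mouth 1a (0.0502), and the second without ventral 2 (0.0536). A probe set without a gene symbol was also higher. It had signals of 588 ± 194, 20.9 ± 2.01 and 76.2 ± 13.1 (log2 fold changes 3.99 ± 0.22 and 2.68 ± 0.22) and was picked out after its values were seen.

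**Figure D2:**
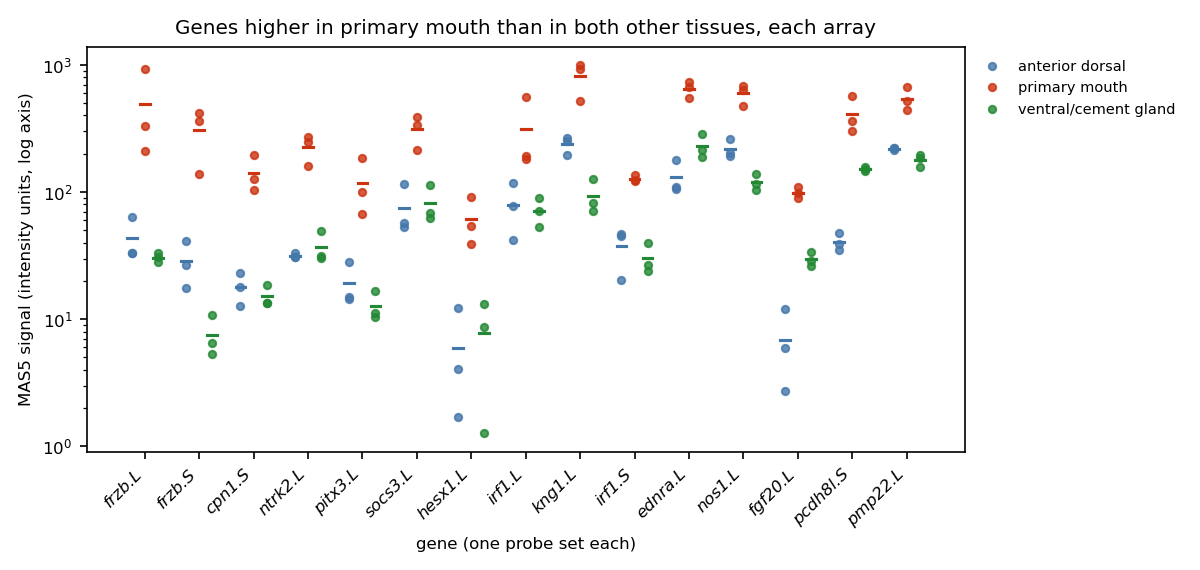
MAS5 signal (log axis) of the 15 named genes with the highest smaller fold change over both flanking tissues, with 1 point per array, coloured by tissue, and a bar at each mean of 3 arrays. For hesx1.L the primary mouth mean is 61.3 against 5.98 and 7.75.

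In all, 116 of 10011 probe sets were higher in primary mouth than in both other tissues, and 73 of these had 1 symbol. With the batch as a term the count was 198 and held all 116. It was 57 within the first batch and 98 within the second, and all 116 kept both directions in each batch. In 100 simulations with no effect in any gene the overlap was at most 0, as these hold next to no calls, and independent lists of the observed sizes would share 20.7. The 3 primary mouth arrays cannot be divided into sets of 2 or more, so part of the excess may come from these shared arrays. The count was 76 without primary mouth 1a and 76 without ventral 2.

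Genes lower in primary mouth than in both other tissues numbered 66, of which 42 had 1 symbol. The synuclein gene sncg.S read 99.5 ± 22.2 in primary mouth against 471 ± 74.6 in anterior dorsal and 510 ± 148 in ventral tissue (log2 fold changes -2.08 ± 0.23 and -2.16 ± 0.23, adjusted p = 9.21e-05 and 6.06e-05). The homeobox gene crx.S, an otx relative, read 15.7 ± 1.84, 115 ± 23.4 and 88.8 ± 26.2 (log2 fold changes -2.03 ± 0.21 and -1.69 ± 0.21, adjusted p = 6.65e-05 and 0.000203). The chemokine gene cxcl14.L differed by -1.58 ± 0.24 and -2.97 ± 0.24, the caveolin gene cav1.L by -1.42 ± 0.21 and -2.39 ± 0.21, and the vesicle GTPase gene rab3a.L by -1.47 ± 0.24 and -2.65 ± 0.24 on the log2 scale. Further genes in this set were the creatine kinase gene ckmt1b.L (-1.33 and -1.52), the monocarboxylate transporter gene slc16a3.L (-1.79 and -1.30), tbx5.L (-1.07 and -1.42), snn.S (-1.15 and -1.46) and dhx32.L (-1.12 and -1.99). Over these 8 genes adjusted p was 7.66e-06 to 0.0036.

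With the batch as a term 135 probe sets were lower than in both, among them all 66, and each batch alone gave 22 and 64. All 66 kept both directions in each batch. Independent lists of the observed sizes would share 49.2, and simulations with no effect shared at most 1. The count was 38 without anterior dorsal 2 and 39 without anterior dorsal 3.

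**Figure D3:**
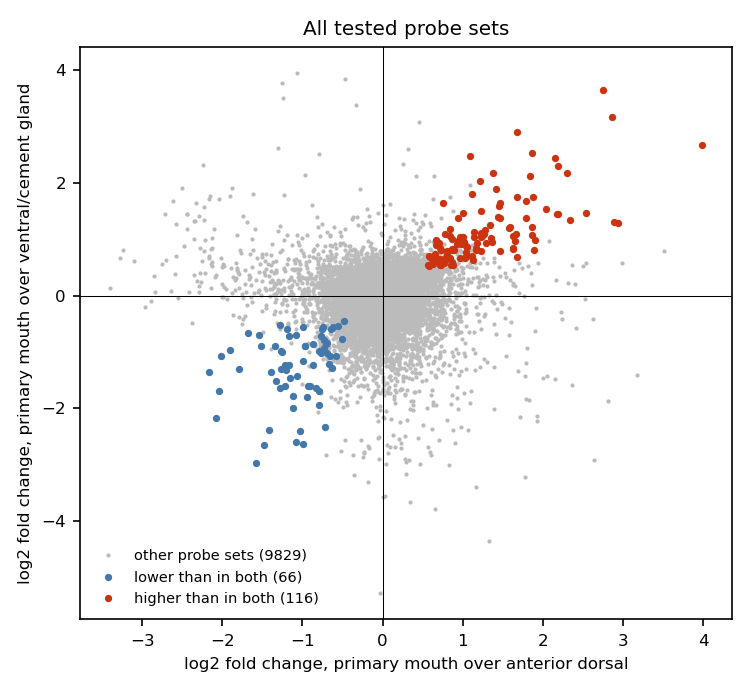
Log2 fold change of primary mouth over anterior dorsal tissue (x axis) against that over ventral and cement gland tissue (y axis), with 1 point per tested probe set (10011 in all). Red points are the 116 probe sets higher than in both tissues, blue points the 66 lower than in both, and grey points all others.

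The next comparison set primary mouth against anterior dorsal tissue. Most forebrain and neural tube genes were lower in primary mouth, and some members of the heart and ventral blood list and of the foregut and liver list were higher. The T-box gene eomes.L, a marker of the dorsal telencephalon, read 7.42 ± 3.64 (SD, n = 3) in primary mouth and 230.2 ± 31.4 in anterior dorsal tissue, a log2 fold change of -3.40 ± 0.19 (adjusted p = 2.35e-06). Transferrin, tf.L, read 217 ± 44.3 and 9.55 ± 2.79 (log2 fold change 3.18 ± 0.19, adjusted p = 3.68e-06). In all, 957 probe sets differed, 469 higher and 488 lower in primary mouth.

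Among the 10 genes with the largest decrease were ttyh1.L (-3.27 ± 0.25), the neuronal intermediate filament gene prph.S (-3.24 ± 0.24) and its homeolog prph.L (-2.70 ± 0.17), the retinal gene rgr.S (-2.96 ± 0.19) and the forebrain homeobox gene emx2.L (-2.89 ± 0.32). The transcription factor genes hes7.1.L (-2.84 ± 0.23), dmrta2.S (-2.72 ± 0.21) and foxb1.S (-2.59 ± 0.17) and the neuronal splicing factor gene nova2.L (-2.45 ± 0.22) were likewise lower, with adjusted p of 4.42e-06 to 0.000102. The genes with the largest increase included the complement genes c8a.L (2.99 ± 0.23) and cfi.S (2.62 ± 0.21) and the protease inhibitors a2m.S (2.53 ± 0.20) and a2ml1.L (2.53 ± 0.24). The signal of a2m.S was 3320 ± 351 in primary mouth against 560.1 ± 41.0. The heart and pharynx homeobox gene nkx2-5.S read 157 ± 57.7 against 7.91 ± 3.55 (2.81 ± 0.26), and the transporter gene slc5a8.1.L 149 ± 100.2 against 7.43 ± 2.93 (2.64 ± 0.34). For these 6 genes adjusted p was 1.17e-05 to 0.000277.

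The forebrain and neural tube list was lower in primary mouth, and the eye, Wnt and cell cycle lists passed camera only at its preset correlation. Of 31 tested forebrain and neural tube genes, 25 were lower, 2 higher and 4 not past the threshold (2 higher and 26 lower adjusted over the list alone, camera adjusted p = 1.33e-22, adjusted p = 0.00818 with an estimated correlation). Lower members included pax6.L (-2.44), the neuronal tubulin gene tubb3.L (-2.38) and pou3f2.S (-2.22), and the 2 higher ones were the homeologs of dlx2, which is also a neural crest gene. Of 16 eye and lens genes 8 were lower and 1 was higher (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.86e-05, adjusted p = 0.0699 with an estimated correlation). The higher gene was pitx3.L, and the lower ones included vsx1.L (-1.46). Wnt pathway genes went both ways, with 9 of 27 lower and 4 higher (6 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.0699 with an estimated correlation). Both frzb copies were among the higher genes, and wnt8a.L (-1.999), wnt3a.S (-1.90) and the receptor gene fzd10.S (-1.79) among the lower ones. Of 42 cell cycle genes 4 were lower and 38 did not pass (11 lower adjusted over the list alone, 11 lower with the batch as a term, camera adjusted p = 2.1e-06, adjusted p = 0.0654 with an estimated correlation). Those 4 were the replication gene cdc6.S (-1.05 ± 0.17, adjusted p = 0.0015) and mcm4.L, mcm4.S and rrm1.L. The calls of the last 3 were lost without primary mouth 2 (adjusted p = 0.125, 0.102 and 0.143), anterior dorsal 2 (0.155, 0.106 and 0.155) or anterior dorsal 3 (0.11, 0.121 and 0.139), and some also without primary mouth 1a (0.0666 for mcm4.S, 0.12 for rrm1.L), ventral 2 (0.0523 for mcm4.L, 0.0559 for rrm1.L) or ventral 3 (0.0546 for rrm1.L).

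**Figure D4:**
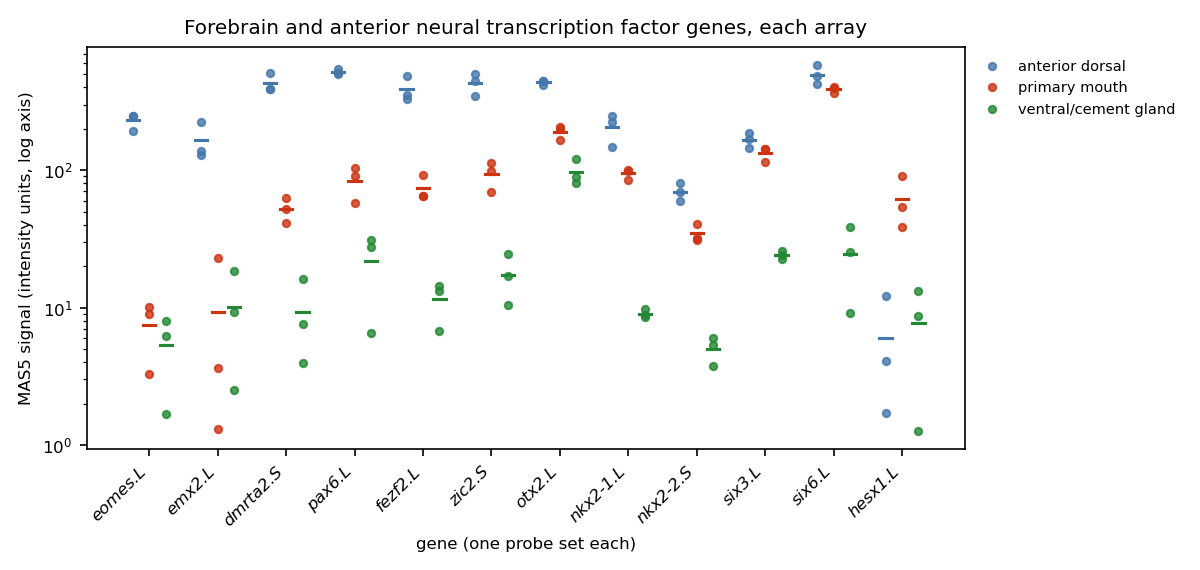
MAS5 signal (log axis) of 12 forebrain and anterior neural transcription factor genes, with 1 point per array, coloured by tissue, and a bar at each mean of 3 arrays. For eomes.L the primary mouth mean is 7.42 against 230.2 in anterior dorsal tissue, and for six6.L it is 389 against 496.

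In this contrast 8 lists passed camera as higher in primary mouth than in anterior dorsal tissue. The heart and ventral blood list and the foregut and liver list kept the call with an estimated correlation. The others did not. Of 18 primary mouth and anterior ectoderm genes 9 were higher and 4 lower (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000272, adjusted p = 0.0699 with an estimated correlation). The homeobox gene pitx1.L was higher (2.36 ± 0.20, adjusted p = 2.09e-05), and otx1.L (-1.28) and otx2.L (-1.13 ± 0.17, adjusted p = 0.000981) were lower. For otx2.S the change was -1.03 ± 0.28 (adjusted p = 0.0392), and the call was lost without anterior dorsal 2 (0.15) or 3 (0.16), primary mouth 1a (0.125) or 2 (0.148), or ventral 1 (0.0516), 2 (0.0632) or 3 (0.054). The Hedgehog ligand gene shh.L read 214 ± 106 against 122 ± 9.55 and did not pass (adjusted p = 0.235), and frzb2.L had signals of 7.41 to 12.6 in the 3 tissues and was not tested. Of 9 cement gland genes 4 were higher and 5 not past (5 higher and 3 lower adjusted over the list alone, 5 higher and 3 lower with the batch as a term, camera adjusted p = 0.0226, adjusted p = 0.176 with an estimated correlation). The disulfide isomerase gene agr2 was higher in both copies, agr2.L by 1.999 ± 0.27 and agr2.S by 1.93 ± 0.38, while its relative ag1.S did not pass (adjusted p = 0.192). The call of ag1.L (0.84 ± 0.21, adjusted p = 0.0271) was lost without anterior dorsal 1 (0.0709), 2 (0.0691) or 3 (0.0916) or primary mouth 3 (0.0635).

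Of 18 epidermal genes 4 were higher, all keratins, such as krt18.1.L (2.24) and krt19.L (1.91) (4 higher adjusted over the list alone, 7 higher and 1 lower with the batch as a term, camera adjusted p = 0.000943, adjusted p = 0.115 with an estimated correlation). Of 19 cranial neural crest genes 6 were higher and 1 was lower (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00335, adjusted p = 0.115 with an estimated correlation). Examples were dlx2.S (1.87) and snai1.S (1.66) against pax3.S (-2.24). Of 16 heart and ventral blood genes 7 were higher and 1 lower (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.63e-05, adjusted p = 0.0479 with an estimated correlation). Beside nkx2-5.S the higher genes included nkx2-3.S (1.91) and the endothelial gene fli1.S (1.90). Of 10 foregut and liver genes 3 were higher and 1 lower (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.0479 with an estimated correlation). They were led by a2ml1.L and a2m.S and included sox17a.L (1.45), which is also in the endothelial group below, while nkx2-1.L was lower (-0.97). Primitive myeloid genes were higher in 5 of 15 cases and lower in 1 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000913, adjusted p = 0.0699 with an estimated correlation). The peroxidase gene mpo.S (1.72) and cyba.L (1.39) were higher and cxcr4.L lower (-2.13). Of 13 matrix proteases and inhibitors 4 were higher (4 higher adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.184 with an estimated correlation). The call of mmp28.L (1.11) held without each array. That of mmp1.S was lost in 4 alternative fits, among them that without anterior dorsal 2 (adjusted p = 0.0712). That of timp2.L was lost without anterior dorsal 2 (0.0746) or 3 (0.092) or primary mouth 1a (0.0754) or 2 (0.0614). The call of mmp11.L was lost in 9 alternative fits. Among them were those without anterior dorsal 1 (0.088), 2 (0.108) or 3 (0.0927), primary mouth 1a (0.138) or 2 (0.139) or ventral 2 (0.0525).

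The remaining lists did not pass camera in this contrast. Retinoic acid genes split, with 3 of 13 higher and 3 lower (3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.299, adjusted p = 0.546 with an estimated correlation). The receptor gene rarg.S (2.50 ± 0.18) and the degrading enzyme gene cyp26c1.S (1.58 ± 0.22) were higher, and nr2f1.L was lower (-2.001 ± 0.20). In the Hedgehog list 1 of 8 was higher and 3 were lower (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.142, adjusted p = 0.331 with an estimated correlation). The pathway inhibitor gene hhip.L was higher (0.81), and gli3.L (-1.42) and nkx2-2.S (-0.76) were lower. Of 10 FGF genes 2 were higher, fgf20.L and fgf8.L (0.93), and 2 lower (3 higher and 3 lower adjusted over the list alone, 4 higher and 3 lower with the batch as a term, camera adjusted p = 0.464, adjusted p = 0.638 with an estimated correlation). Of 24 BMP and TGF-beta genes 3 were higher, among them the antagonist nog.L (1.23) (5 higher adjusted over the list alone, 8 higher with the batch as a term, camera adjusted p = 0.116, adjusted p = 0.454 with an estimated correlation). With the batch as a term this list passed (adjusted p = 0.0297). Of 18 matrix genes 2 were higher and 2 lower (5 higher and 4 lower adjusted over the list alone, 4 higher and 4 lower with the batch as a term, camera adjusted p = 0.813, adjusted p = 0.867 with an estimated correlation). The higher genes were has2.S (1.94) and vcan.L (1.63), and dag1.L (-1.45) was lower.

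Of 18 genes of ciliated cells and ionocytes 2 were higher, such as tekt2.S (0.93), and 1 lower (3 higher and 1 lower adjusted over the list alone, 4 higher and 1 lower with the batch as a term, camera adjusted p = 0.363, adjusted p = 0.617 with an estimated correlation). Muscle and notochord genes numbered 7, with 1 higher and 1 lower (2 higher and 1 lower adjusted over the list alone, 2 higher and 2 lower with the batch as a term, camera adjusted p = 0.886, adjusted p = 0.925 with an estimated correlation). These were the troponin gene tnni2.S (0.97) and the notochord homeobox gene not.L (-2.01). Their median (-0.02) and mean were below 0 while camera's direction was up. In the heat shock and stress list 1 of 17 was lower (1 lower adjusted over the list alone, 2 higher and 2 lower with the batch as a term, camera adjusted p = 0.846, adjusted p = 0.867 with an estimated correlation). By limma, 0 of 9 apoptosis genes passed (0 by limma adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 higher and 1 lower with the batch as a term, camera adjusted p = 0.752, adjusted p = 0.867 with an estimated correlation). The same held for the 3 tested Hox genes, with log2 fold changes of 0.32 for hoxa2.L, 0.20 for hoxa2.S and 0.22 for hoxa3.S (0 at an unadjusted p under 0.05).

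With the batch as a term 1603 probe sets (791 higher) differed between primary mouth and anterior dorsal tissue, among them all 957, and 514 and 806 differed within the first and the second batch. All 957 had the same direction in both batches, and the 12 lists called had medians in camera's direction in both. The count was 618 (292 higher) without anterior dorsal 2 and 608 (282 higher) without anterior dorsal 3. The cement gland call was lost without primary mouth 3 (adjusted p = 0.051), and the protease call without anterior dorsal 1 (0.104) or primary mouth 2 (0.0753).

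Against ventral and cement gland tissue, primary mouth was lower in many heart genes and in genes of myeloid cells and ionocytes. It was higher in genes of the forebrain and of anterior ectoderm. The mucin-like gene muc2l.L read 59.6 ± 15.6 (SD, n = 3) in primary mouth and 1545 ± 448 in ventral tissue, a log2 fold change of -4.35 ± 0.30 (adjusted p = 3.14e-06). The eye-field homeobox gene six6.L read 389 ± 21.3 and 24.5 ± 14.9 (3.39 ± 0.25, adjusted p = 4e-06). In all, 1452 probe sets differed, 442 higher and 1010 lower in primary mouth.

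The largest increases included the secretory protein gene crisp1.5.S (3.95 ± 0.55) and the astacin-like protease genes astl3a.1.L (3.85 ± 0.60) and astl2e.2.L (3.51 ± 0.33). The signal of crisp1.5.S was 2455 ± 651 in primary mouth and 193 ± 142 in ventral tissue. Beside frzb and kng1.L, the head mesenchyme homeobox gene alx1.L (3.08 ± 0.19), the proton channel gene otop3.L (2.62 ± 0.39) and the retinoic acid synthesis gene aldh1a2.L (2.60 ± 0.20) were among the 10 largest. Adjusted p over these 6 genes was 1.62e-06 to 0.000977. Among the 10 largest decreases were the cornifelin gene cnfn.1.S (-3.80 ± 0.25), the endoderm and heart factor gata6.L (-3.66 ± 0.26), the heart factor hand1.L (-3.56 ± 0.15) and hes5.10.L (-3.19 ± 0.18). They also included the hyaluronan synthase gene has1.S (-2.996 ± 0.37), val.L (-2.96 ± 0.20), cxcl14.L and slc5a8.1.L (-2.91 ± 0.34), with adjusted p of 3.15e-07 to 0.000202 for these 8.

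Of the lists that passed camera as lower in primary mouth, those of the heart, myeloid cells and ciliated cells and ionocytes kept the call with an estimated correlation and the others did not. Of 16 heart and ventral blood genes 11 were lower and 1 was higher (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 6.11e-08, adjusted p = 0.027 with an estimated correlation). Examples were gata4.L (-2.80), hand2.S (-2.57) and the cardiac troponin gene tnni3.L (-2.78), against fli1.S (0.99). The members lmo2.S (0.21), aplnr.L (-0.13) and aplnr.S (0.05), grouped below as endothelial, did not pass (limma adjusted p = 0.616 to 0.898). In this list the log2 fold change of nkx2-5.S was -1.88 ± 0.26 (adjusted p = 0.000464). Of 15 myeloid genes 11 were lower and 1 higher (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 7.59e-09, adjusted p = 0.0246 with an estimated correlation). The largest decreases were those of mpo.L (-2.39) and cebpa.L (-2.37). Of 18 genes of ciliated cells and ionocytes 11 were lower and 1 higher (2 higher and 12 lower adjusted over the list alone, 2 higher and 13 lower with the batch as a term, camera adjusted p = 6.11e-08, adjusted p = 0.0479 with an estimated correlation). Lower were the proton pump genes atp6v1b1.L (-2.91) and atp6v0a4.L (-2.04) and the carbonic anhydrase gene ca2.S (-2.80). Of 24 BMP and TGF-beta genes 12 were lower and 2 higher (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 8.2e-05, adjusted p = 0.106 with an estimated correlation). Decreases were led by bambi.L (-1.77), bmp2.L (-1.71) and ventx2.1.S (-1.59), and the increases were in tgfbi.L (2.13) and the antagonist nog.L (1.11).

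Of 10 foregut and liver genes 5 were lower, such as gata5.L (-2.71) and gata5.S (-2.69), and 2 higher, among them nkx2-1.L (2.14) (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0399, adjusted p = 0.115 with an estimated correlation). Of 9 cement gland genes 4 were lower (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0396, adjusted p = 0.198 with an estimated correlation). They were ag1.L (-1.39 ± 0.21), ag1.S (-1.77 ± 0.26), agr2.L (-1.47 ± 0.27) and agr2.S (-2.13 ± 0.38), with adjusted p of 0.000685 to 0.00274. Of 13 matrix proteases 3 were lower, such as mmp1.S (-1.94), and 1, mmp28.L (1.80), higher (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.184 with an estimated correlation). Of 18 epidermal genes 2 were lower (3 lower adjusted over the list alone, 2 higher and 4 lower with the batch as a term, camera adjusted p = 0.0445, adjusted p = 0.308 with an estimated correlation). They were dlx3.L (-0.75), lost without ventral 2 (adjusted p = 0.0585) or 3 (0.0591), and trim29.L (-0.81), lost without primary mouth 1a (0.0599) or ventral 3 (0.0617). All 3 tested Hox genes were lower, among them hoxa3.S (-2.25 ± 0.18) (3 lower adjusted over the list alone).

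Of the lists that passed camera as higher in primary mouth than in ventral tissue, those of the primary mouth and the forebrain kept the call with an estimated correlation and the others did not. Of 18 primary mouth and anterior ectoderm genes 13 were higher and 1 lower (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.82e-10, adjusted p = 0.0246 with an estimated correlation). Higher genes included shh.L (1.72 ± 0.30, adjusted p = 0.00198) and otx2.L (0.89 ± 0.17, adjusted p = 0.00382). The fixed genes pitx1.L (0.55 ± 0.20, adjusted p = 0.0924) and otx2.S (0.47 ± 0.28, adjusted p = 0.311) did not pass. Of 31 forebrain and neural tube genes 16 were higher and 15 did not pass (17 higher adjusted over the list alone, camera adjusted p = 1.52e-08, adjusted p = 0.027 with an estimated correlation). Among them were six3.L (1.89), zic2.S (1.71) and fezf2.L (1.71). Of 42 cell cycle genes 10 were higher, such as mcm4.S (0.71) and ccnd1.S (0.91) (12 higher adjusted over the list alone, 19 higher with the batch as a term, camera adjusted p = 1.86e-05, adjusted p = 0.0699 with an estimated correlation). Of 8 Hedgehog genes 4 were higher, among them nkx2-2.S (1.26) (5 higher adjusted over the list alone, camera adjusted p = 0.000219, adjusted p = 0.0654 with an estimated correlation). Of 13 retinoic acid genes 3 were higher, among them aldh1a2.L and cyp26c1.S (1.21) (4 higher adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.184 with an estimated correlation).

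Among lists that did not pass camera here, eye and lens genes went both ways, with 6 of 16 higher and 5 lower, such as tbx3.S (-2.66) (7 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.813, adjusted p = 0.886 with an estimated correlation). Of 19 neural crest genes 6 were higher and 3 lower (6 higher and 4 lower adjusted over the list alone, 6 higher and 5 lower with the batch as a term, camera adjusted p = 0.52, adjusted p = 0.666 with an estimated correlation). The increases were largest for pax3.S (2.32) and sox9.S (1.74). Of 27 Wnt genes 4 were higher and 2 lower, among the latter sfrp2.S (-1.22) (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.813, adjusted p = 0.827 with an estimated correlation). Their median was -0.28, their mean 0.14 and camera's direction down. Matrix genes were higher in 4 of 18 cases and lower in 1 (5 higher and 2 lower adjusted over the list alone, 6 higher and 3 lower with the batch as a term, camera adjusted p = 0.166, adjusted p = 0.352 with an estimated correlation). They included sparc.L (0.96) and col9a1.L (0.93), against cd44.L (-0.89). Of 10 FGF genes 1, fgf20.L, was higher (2 higher adjusted over the list alone, 3 higher with the batch as a term, camera adjusted p = 0.201, adjusted p = 0.454 with an estimated correlation). Of 7 muscle and notochord genes 2 were higher, shh.L and tnni2.S (0.96), and 1 lower (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.177, adjusted p = 0.445 with an estimated correlation). Of 9 apoptosis genes 1 was lower (1 lower adjusted over the list alone, camera adjusted p = 0.379, adjusted p = 0.638 with an estimated correlation). Of 17 stress genes 1 was higher and 1, hmox1.S (-1.73), lower (2 higher and 1 lower adjusted over the list alone, 3 higher and 1 lower with the batch as a term, camera adjusted p = 0.502, adjusted p = 0.591 with an estimated correlation).

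**Figure D5:**
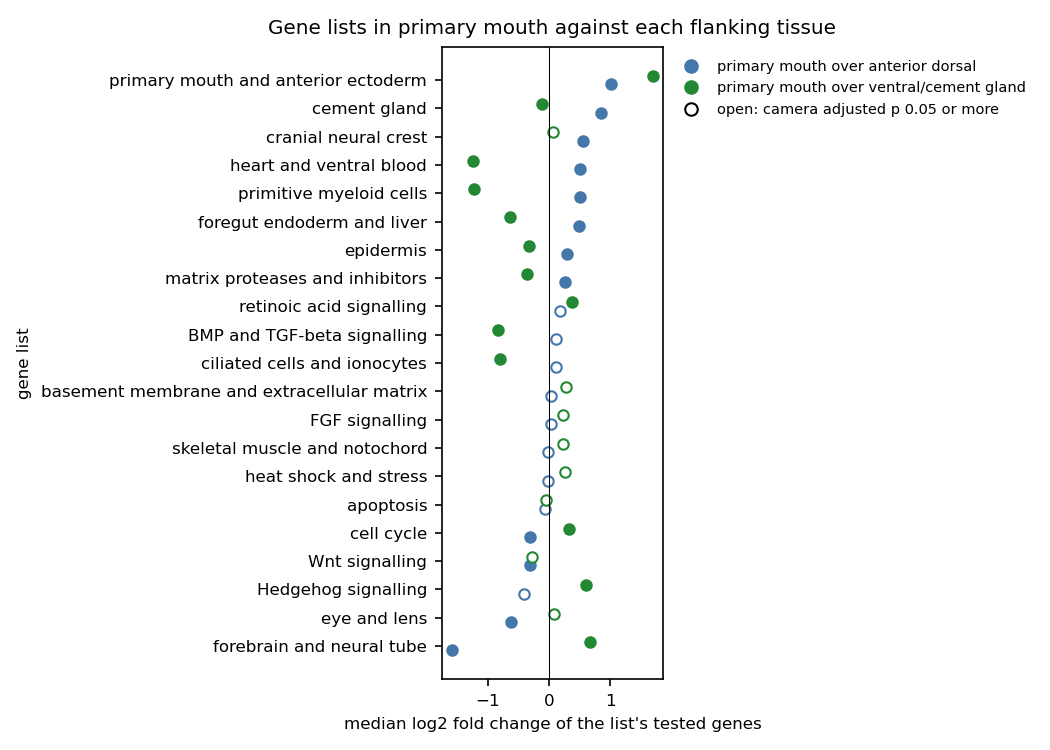
Median log2 fold change of the tested genes of each list in primary mouth over anterior dorsal tissue (blue) and over ventral and cement gland tissue (green), with filled points for camera adjusted p under 0.05 and open points otherwise. Forebrain and neural tube genes have medians of -1.59 and 0.66, and heart and ventral blood genes 0.51 and -1.24.

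With the batch as a term 2258 probe sets (877 higher) differed between primary mouth and ventral tissue, among them all 1452, and 760 and 1263 differed within the first and the second batch, with all 1452 in the same direction in both. The 13 lists called had medians in camera's direction in both batches, and the epidermal list lost its call with the batch as a term (adjusted p = 0.0833). The count was 955 without ventral 3, and that of the higher probe sets was 237 without ventral 3, 264 without ventral 2, 292 without primary mouth 1a and 671 without primary mouth 3. List calls were lost for the epidermis without primary mouth 1a (0.0863) or 2 (0.108) or ventral 1 (0.0625) or 3 (0.166), for the foregut without anterior dorsal 3 (0.0616), primary mouth 3 (0.0571) or ventral 1 (0.0581), for the cement gland without ventral 1 (0.134) and for the proteases without primary mouth 3 (0.0652). Without primary mouth 3 the muscle and notochord list passed (0.0456).

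The last comparison set both flanking tissues against each other and showed the largest differences. Anterior dorsal tissue was higher in neural and cell cycle genes, and ventral tissue in genes of the heart and ventral blood, myeloid and foregut lists. The paired homeobox gene pax3.S, a marker of dorsal neural tube and neural crest, read 794 ± 85.0 (SD, n = 3) in anterior dorsal and 19.9 ± 12.6 in ventral tissue, a log2 fold change of 4.56 ± 0.25 (adjusted p = 2.7e-07). For muc2l.L the signals were 15.5 ± 13.8 and 1545 ± 448 (-5.68 ± 0.30, adjusted p = 2.16e-07). In all, 2469 probe sets differed, 1054 higher in anterior dorsal and 1415 higher in ventral tissue.

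Further genes higher in anterior dorsal tissue were crisp1.5.S (5.01 ± 0.55), astl2e.2.L (4.76 ± 0.33), astl3a.1.L (4.32 ± 0.60), otop3.L (3.92 ± 0.39), dmrta2.S (4.16 ± 0.21), prph.S (4.04 ± 0.24), the neuronal gene dpysl3.L (3.97 ± 0.21), ttyh1.L (3.94 ± 0.25) and pax6.L (3.90 ± 0.27), with adjusted p of 1.9e-07 to 0.000194. Higher in ventral tissue were slc5a8.1.L (-5.55 ± 0.34), nkx2-5.S (-4.69 ± 0.26), tf.L (-4.58 ± 0.19), cnfn.1.S (-4.45 ± 0.25), the galectin gene lgals4.2.L (-4.15 ± 0.25), agr2.S (-4.06 ± 0.38), gata6.L (-4.003 ± 0.26) and the myeloperoxidase gene mpo.S (-3.87 ± 0.18), with adjusted p of 9.2e-08 to 9.54e-06. Primary mouth means lay between those of the flanking tissues for 907 of the 1054 probe sets higher in anterior dorsal tissue (86.1%) and for 964 of the 1415 higher in ventral tissue (68.1%). These counts use direction alone among probe sets chosen for a flank difference, which itself favours a middle position. Primary mouth differed from both flanking tissues in 80 of the 907 and 89 of the 964. It differed from ventral tissue only in 168 of the 1054 and 694 of the 1415, and from anterior dorsal tissue only in 306 and 205.

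Of 31 forebrain and neural tube genes 29 were higher in anterior dorsal tissue, and 2 were lower (29 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.68e-22, adjusted p = 0.00818 with an estimated correlation). The lower genes were the dlx2 homeologs, and the higher ones included fezf2.L (3.87) and zic2.S (3.75). Of 42 cell cycle genes 27 were higher, such as cdc6.S (1.53) and ccnd1.S (1.44) (31 higher adjusted over the list alone, camera adjusted p = 1.07e-10, adjusted p = 0.027 with an estimated correlation). Of 16 eye and lens genes 8 were higher, such as six6.L (3.72), and 3 lower (8 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00383, adjusted p = 0.171 with an estimated correlation). Of 18 primary mouth and anterior ectoderm genes 8 were higher and 4 lower (9 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0396, adjusted p = 0.198 with an estimated correlation). The otx genes otx1.L (2.51) and otx2.L (2.02) were higher and pitx1.L lower (-1.81). Of 8 Hedgehog genes 5 were higher, such as nkx2-1.L (3.12) (6 higher adjusted over the list alone, camera adjusted p = 0.000471, adjusted p = 0.0699 with an estimated correlation). The call of shh.L (1.09 ± 0.30, adjusted p = 0.0169) was lost without anterior dorsal 2 (0.061) or ventral 3 (0.0722). Of 27 Wnt genes 9 were higher, such as tcf7l2.L (1.94), and 2 lower (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.0833 with an estimated correlation).

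Of 16 heart and ventral blood genes 14 were lower in anterior dorsal than in ventral tissue, such as hand1.L (-3.59) (14 lower adjusted over the list alone, camera adjusted p = 1.06e-12, adjusted p = 0.0167 with an estimated correlation). Of 15 myeloid genes 12 were lower, such as cyba.L (-3.40), and 1, cxcr4.L (3.15), higher (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 4.5e-08, adjusted p = 0.027 with an estimated correlation). Of 10 foregut and liver genes 8 were lower, such as gata5.S (-3.25), and 2 higher (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 3.63e-05, adjusted p = 0.027 with an estimated correlation). Of 18 genes of ciliated cells and ionocytes 13 were lower, such as atp6v1b1.L (-3.19), and 1 higher (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 6.58e-08, adjusted p = 0.0479 with an estimated correlation). Of 9 cement gland genes 5 were lower and 2 higher (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00693, adjusted p = 0.115 with an estimated correlation). Lower genes included agr2.L (-3.47), ag1.L (-2.23) and ag1.S (-2.37). Epidermal genes were lower in 8 of 18 cases, such as krt18.1.L (-2.66) (10 lower adjusted over the list alone, 1 higher and 14 lower with the batch as a term, camera adjusted p = 3.63e-05, adjusted p = 0.0718 with an estimated correlation). Of 24 BMP and TGF-beta genes 13 were lower, such as bmp2.L (-2.10), and 1, tgfbi.L (1.48), higher (2 higher and 13 lower adjusted over the list alone, 2 higher and 16 lower with the batch as a term, camera adjusted p = 3.93e-05, adjusted p = 0.0954 with an estimated correlation). Of 13 matrix proteases 6 were lower, such as mmp1.S (-2.60), and 1 higher (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00335, adjusted p = 0.115 with an estimated correlation).

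Lists that did not pass camera between the flanking tissues began with the cranial neural crest, in which 2 of 19 genes were higher and 6 lower, such as hand2.S (-3.27) (3 higher and 7 lower adjusted over the list alone, 3 higher and 10 lower with the batch as a term, camera adjusted p = 0.0505, adjusted p = 0.246 with an estimated correlation). It passed with the replicate number as a block (adjusted p = 0.0355) and with the batch as a term (0.0279), and also without primary mouth 1a (0.0481), 2 (0.0456) or 3 (0.0369) or ventral 1 (0.035). Retinoic acid genes were higher in 3 of 13 cases and lower in 2 (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.464, adjusted p = 0.639 with an estimated correlation). Examples in each direction were nr2f1.L (2.50) and rarg.S (-1.97). Of 10 FGF genes 3 were higher, such as fgfr1.L (1.15), and 2 lower, such as fgf20.L (-1.01) (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.994, adjusted p = 0.996 with an estimated correlation). Their median was -0.17 and their mean 0.04. Matrix genes divided into 4 higher, such as dag1.L (1.55), and 2 lower, such as vcan.L (-0.79), of 18 (5 higher and 3 lower adjusted over the list alone, 6 higher and 4 lower with the batch as a term, camera adjusted p = 0.447, adjusted p = 0.604 with an estimated correlation). Of 7 muscle and notochord genes 2 were higher and 1, ckm.L (-1.48), lower (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.203, adjusted p = 0.454 with an estimated correlation). Of 17 stress genes 3 were higher, such as hsph1.L (0.83), and 1 lower (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.537, adjusted p = 0.617 with an estimated correlation). Of 9 apoptosis genes 1 was higher and 2 lower, among them casp10.L (-1.02) (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.731, adjusted p = 0.865 with an estimated correlation). Their median was 0.05, their mean -0.15 and camera's direction down. All 3 tested Hox genes were lower in anterior dorsal tissue, among them hoxa3.S (-2.46 ± 0.18) (3 lower adjusted over the list alone).

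With the batch as a term 3683 probe sets (1775 higher) differed between the flanking tissues, among them all 2469, and 3017 differed within the second batch. The first batch has 1 array of each flanking tissue, so a count from a test within it carries no weight and is left out here. In both batches 2468 of the 2469 had the same direction. The 14 lists called had medians in camera's direction in both batches. The primary mouth list lost its call without anterior dorsal 2 (adjusted p = 0.056) or ventral 2 (0.0638), and the Wnt list without ventral 1 (0.0525).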

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

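The fit with the batch as a term was chosen only after the result was seen, and the other tests of this part before. The beta-actin control ratio and the batches it marks stood out in control probe sets that the comparisons do not use. The lowest 3' to 5' ratio among the 4 arrays of the high batch was 5.48, against at most 2.03 in the other 5. Between these batches 2565 probe sets differed.

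The genes higher, or lower, in primary mouth than in both flanking tissues were set against uneven batches, shared arrays and other groupings. All 116 higher ones kept both calls with the batch as a term, but this was likely in advance. Each tissue has arrays of both batches, so a batch difference adds to the spread of the main fit and leaves few calls. Keeping the calls therefore cannot serve as a test of uneven batches as their source. Simulations without any effect gave an overlap of at most 0 higher and 1 lower, but they hold next to no calls (means of 0.09 and 0.08 for the 2 contrasts), so they cannot show how far the shared primary mouth arrays raise the overlap among genes that differ. In 100 drawn splits of the 9 arrays into 3 groups of 3, 3 gave as many genes higher than in both, the real one included, and 3 as many lower, with 752 and 222 as the highest other counts. The 2 other large splits in each direction set the 3 ventral arrays apart as a group, which reflects tissue structure. A further split set the primary mouth arrays apart but mixed the flanking ones, and gave 15 higher and 5 lower. The 96 splits whose group set against the others was of mixed tissues gave at most 0 genes. Mixing tissues puts their differences into the spread, which leaves few calls whatever the overlap, so these splits cannot exclude chance. Limma tested the difference between tissues in each contrast, and its p-values measure only the spread between these samples. Simulated noise, independent between genes, gave at most 0 higher and 1 lower against the 116 and 66 found. This argues against such noise alone as the source of the whole sets. How far the shared arrays raise the counts, and chance with noise shared between genes, stay open.

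Pairwise counts were set against the 10 splits of the 6 arrays of each contrast, which are too few for a share under 0.05. For primary mouth and anterior dorsal tissue 1 of the 10, the real one, gave 957 and the highest other 1. The real split against ventral tissue gave 1452 (again 1 of 10) and that between the flanking tissues 2469 (1 of 10), with at most 0 in any other split by limma, including those that part all 3 numbered pairs. For the gene lists 1 of 100 splits, the real one, gave as many as 39 calls among 63 tests, with 35 as the highest other. The other 11 splits that kept a whole tissue together gave up to 35, and the 88 mixed ones up to 28 (median 14.5). Since other splits also gave many calls, the rank of the real one cannot exclude chance for the list calls. Single list calls are less certain than their adjusted p.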

How the results depend on the processing

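The fits by batch and the list tests without each array were chosen only after the result was seen, and the other alternatives before. For the comparisons of primary mouth with anterior dorsal tissue, with ventral tissue, and of the flanking tissues with each other, and for the genes higher and lower than in both, the counts were 957, 1452, 2469, 116 and 66. They kept within 1.5 times of these under quantile normalization (981, 1490, 2517, 126, 58), offsets of 1 (930, 1413, 2439, 107, 71) and 64 (945, 1445, 2473, 125, 57), no filter (1017, 1463, 2730, 110, 58), the stricter filter (656, 1095, 1790, 93, 47), no variance trend (957, 1439, 2484, 113, 66) and only 2 tissues in the fit (789, 1143, 2693, 82, 45). With the replicate block the counts were 1654, 2352, 3333, 222 and 150. Whether the numbers pair primary mouth samples with the others could not be settled. Primary mouth 2 correlated at -0.23 with anterior dorsal 2 and at 0.45 with anterior dorsal 1, but its same-numbered partners lie in the other batch. Primary mouth 3 correlated at 0.58 with anterior dorsal 3 and 0.36 with anterior dorsal 2. With ventral 3 and ventral 2 it correlated at 0.57 and 0.18. In the pairing of anterior dorsal and ventral samples the block lost no call of a named gene and changed no list call other than that of the neural crest. The batch term gave 1603, 2258, 3683, 198 and 135, the high-ratio batch alone 514, 760, 1043, 57 and 22, and the other batch alone 806, 1263, 3017, 98 and 64. In the high-ratio batch the spread comes only from 2 primary mouth arrays, so its 1043 for 1 array against 1 carries no weight, and in the other batch it comes from the flanking tissues. A minimum of 2-fold left 492, 638, 1097, 47 and 23 by its construction. Leaving out each array gave ranges of 608 to 1127, 955 to 1727, 1858 to 2711, 76 to 159 and 38 to 85. Apart from the 2-fold minimum, the causes of these shifts were not tested. Of 428 called results of named genes, settings other than leaving out arrays or the batches alone lost at most 22. The stricter filter tested only 351 of the 428 and lost 1 of these. Leaving out arrays lost 9 to 38 (members of the gene lists among them), and in all settings 0 reversed. List calls numbered 39 of 63, 14 with an estimated correlation and 36 to 39 without each array. The replicate block also lost the calls against ventral tissue of the cement gland (adjusted p = 0.071) and foregut (0.089) lists. With no filter the neural crest list against anterior dorsal tissue (0.21), the protease list against ventral tissue (0.09) and, between the flanking tissues, the primary mouth (0.0561) and Wnt (0.126) lists lost their calls, and the BMP list against anterior dorsal tissue gained a call (0.0217). Signal over background is not known for the low signals, and the added 16 units shrink their fold changes.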

Other observations

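The tests of carry-over, of heart and myeloid markers and of the stress list were chosen only after the result was seen, as were the gene groups described first. All 13 tested genes of the dorsal telencephalon and roof were lower in primary mouth than in anterior dorsal tissue, among them eomes.L, emx2.L, wnt8b.S (-1.71 ± 0.19) and zic5.S (-1.69 ± 0.28), and 7 of them were higher and 1, wnt3a.S (-0.97, adjusted p = 0.04), lower than in ventral tissue. The call of wnt3a.S against ventral tissue was lost without anterior dorsal 3 (adjusted p = 0.0546), primary mouth 1a (0.117) or 3 (0.0882) or ventral 2 (0.07) or 3 (0.166). Among the 7 higher genes, lhx2.L lost its call without any array other than primary mouth 2 (adjusted p = 0.0539 to 0.163) and zic1.S without primary mouth 2 (0.0542) or ventral 3 (0.0683). Of 8 genes of the hypothalamus and optic field, 8 were higher in primary mouth than in ventral tissue, 4 were lower than in anterior dorsal tissue and 1, hesx1.L, was higher. Signals of six3.L were 133 ± 15.8 in primary mouth, 166 ± 21.2 in anterior dorsal and 24.1 ± 1.60 in ventral tissue. Those of foxd1.L were low (16.9, 51.8 and 1.67). It differed by -1.04 ± 0.15 and 0.90 ± 0.15, and each call was lost in 1 alternative fit.

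Of 18 tested genes of complement, coagulation and other plasma proteins, 10 were higher in primary mouth than in anterior dorsal tissue, and against ventral tissue 5 were higher and 4 lower. Among them the complement factor gene cfd.L read 1158 ± 114 in primary mouth, 235 ± 37.4 in anterior dorsal and 1434 ± 307 in ventral tissue, and c9.L was higher than in both (1.28 ± 0.19 and 1.17 ± 0.19). The complement protease gene masp2.S was lower than in ventral tissue (-1.83 ± 0.19). Of 8 genes grouped as endothelial, with sox17a.L of the foregut list among them, 7 were higher than in anterior dorsal tissue. The 3 higher than in both were fli1.S, egfl7.S (1.27 ± 0.21 and 1.09 ± 0.21) and the endothelin receptor gene ednra.L. The last was put in the group after being seen, so it is no separate evidence for endothelium. The hatching gland and secreted astacin-type group holds crisp1.5.S, astl3a.1.L, astl2e.2.L and otop3.L, already seen among the largest increases over ventral tissue. Its count against that tissue is therefore no separate evidence. Of its 8 genes 5 were higher and 1, tll2l.L (-2.86 ± 0.22), lower than in ventral tissue, and 2 were lower than in anterior dorsal tissue. These 2 calls were lost for astl2e.2.L without any anterior dorsal array or primary mouth 1a or 2 (adjusted p = 0.0512 to 0.132), and for xepsin.S without any ventral array, anterior dorsal 2 or 3 or primary mouth 1a or 2 (0.053 to 0.184). The call of xepsin.S against ventral tissue was lost without ventral 3 (0.0694).

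Against a common share of tissue carried over into primary mouth, the rise of each gene over the lower flanking tissue was taken as a share of the difference between the 2 flanking tissues. On the anterior dorsal side 27 of 75 genes with a log2 difference of at least 2 had a share whose 95% interval left out the median of 12.6% (0.938% for eomes.L, 77.2% for six6.L), and on the ventral side 51 of 82 left out that of 11.4% (1.699% for gata6.L, 79.9% for krt19.L), where chance would give 5%, so a single share of either tissue cannot be the whole source of these signals. The share of nkx2-5.S was 24.5% (18.5% in the lowest array) against a median of 1.699% for 9 heart markers, of which tnnc1.L (42.1%) and tnni3.S (34.8%) exceeded it in primary mouth 2. The marker median was at most 3.09% in each array, which argues against heart tissue with all these markers as its whole source, but nkx2-3.L (53.3%) and nkx2-3.S (57.6%) of the heart list, not among the markers, had higher shares, so part of the heart region could be a source. Carry-over of only a part of either tissue would also give unequal shares, so this test does not limit its size. Such a carry-over could remain, and expression in the primary mouth itself was not tested.

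Raised irf1 and socs3 signals were set against blood cells in the dissected piece and a stronger response to dissection. Of 15 tested myeloid genes 11 were lower in primary mouth than in ventral tissue, which argues against myeloid cells as the source of the rise over that tissue, but against anterior dorsal tissue 5 were higher and 1 lower, so they could add to the rise there. The mean log2 change of 17 heat shock and stress genes over both contrasts was 0.053 (95% interval -0.17 to 0.28). That interval takes genes as units and leaves out the spread between samples. No member was higher than in both, but the 4 early response genes of the list (egr1.L, junb.L, ier2.S and jun.L) had changes of 0.254 to 0.905 in both (limma adjusted p = 0.0539 to 0.653). A response to dissection therefore could not be told apart from expression in the tissue, since all 3 tissues were dissected. Of 10 cytokine response genes, a group drawn up from irf1 and socs3, the only other 1 higher than in both was nfkbia.L (1.29 and 0.93), named after its values were seen. Its call against ventral tissue was lost without anterior dorsal 3 (adjusted p = 0.0511), primary mouth 1a (0.114) or ventral 1 (0.0644), 2 (0.129) or 3 (0.0637).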
